A study of Tetrahymena thermophila with 15 samples.

How the data were processed

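RNA-seq libraries of Tetrahymena thermophila strain SB210 were made from total RNA extracted with Trizol, per the labels' protocols. The 15 libraries fall into 5 groups of 3 by their titles: untreated control, silver ion and 3 kinds of nanoparticle named Ag-Cit10, Ag-Cit80 and Ag-PVP80, each treated for 24 h. The values are FPKM per gene (fragments scaled to gene length and library size), given to 2 decimals in 1 table of mRNA and 1 of lncRNA, which the authors deposited with 1 column per library, per the file headers. The submitters' processing notes name cutadapt 2.10, HISAT, StringTie and RSEM, without their roles. The genome build, the annotation and the strand setting are not given in the sources used here, so reads shared between similar or overlapping genes could have been split in ways that cannot be checked. Columns were matched to samples by the sample descriptions, and 0 columns were left without a sample. Of the lncRNA entries above 0, 38 have the same 15 values as an mRNA entry, and 2 of these were tested in both tables, LXLOC_013524 with TTHERM_00663790 and LXLOC_018322 with TTHERM_00648850. Among mRNA genes, 519 entries above 0 repeat the values of another, 2 of them among tested genes. All were kept.

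Everything else was computed from the deposited FPKM. Values were taken as log2(FPKM + 1), a pseudocount of 1, and genes with a mean FPKM of at least 1 over the 15 libraries were kept, 12588 of 23401 mRNA genes and 1779 of 5863 lncRNAs. A fold change is therefore on the log2(FPKM + 1) scale and understates the change of genes at low level. limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend) was fitted to each table with the 5 groups as the only term, so that all 15 libraries shared one estimate of the spread. The comparisons were 4 with the control and 5 between forms of silver. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its table and comparison, two-sided, and calls of at least 2-fold were also counted. The median standard error of a log2 change was 0.17 for mRNA and 0.19 for lncRNA. Intervals of a log2 difference are 95% intervals from the limma fit. The grouping, the tests, the filter, the alternatives from the pseudocount to leaving out each library and the rule for named genes were set before the data were examined.

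Of the 23401 mRNA identifiers, 23376 matched a gene of the reference assembly JCVI-TTA1-2.2 and 25 were MXLOC identifiers; the 5863 LXLOC identifiers of the lncRNA table did not match it. The reference table pairs genes with locus tags and with no other name. The 28 gene lists fixed beforehand (metallothioneins, heat shock proteins, transporters, ribosomal proteins and others) go by product names and matched 0 genes, so the planned camera tests of gene lists and of product families could not be run and no gene function is given. No coordinates are given because the build behind the tables is not stated. Without product names, the rule named per comparison at most 2 mRNA genes that rose and 2 that fell, and at most 3 and 3 lncRNAs, with the largest change among called genes whose 3 values in one group lay clear of the 3 in the other. A further 6 mRNA genes were chosen after their values were seen: MXLOC_008985, TTHERM_00433530, TTHERM_00433520, TTHERM_00241650, TTHERM_000440549 and TTHERM_00529930. The other 3 genes called between Ag-Cit80 and Ag-Cit10, and the genes named for repeated values or for their share of all FPKM, were also named after their values were seen. Some of the 6 genes also met the rule in the comparisons between nanoparticles and silver ion.

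FPKM carries no read totals. Low values of 12020 genes were compared between libraries to see what 1 fragment is worth. Of 178875 values up to 4 fragments, 50.8% lay within 0.15 of a whole multiple, where 30% would by chance, so whole reads were not recovered and no count test was run. The fit was tested on simulated data made by shuffling the residuals of the real libraries with random signs and changing 200 genes per comparison. For Ag-PVP80 against the control, over 12588 genes, it recovered 46% of genes changed 1.5-fold, 80% of those changed 2-fold, 96% at 4-fold and 100% at 8-fold, and called 2 unchanged genes. For silver ion against the control it recovered 34%, 68%, 98% and 100% and called 9 unchanged genes. For Ag-Cit10 against the control it called 52 unchanged genes. Each comparison had a single draw, made from the residuals of all libraries, so these numbers differ by the draw and not by the form of silver. Why a draw gives many such calls was not tested. Chance sharing between comparisons with the same controls was simulated in 100 draws of unchanged groups.

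The alternatives were a pseudocount of 0.1, no filter on low values, median-of-ratios scaling of FPKM with factors from the mRNA table, the replicate number as a block, only the 2 groups compared in the fit, and leaving out each library in turn. Added after seeing the data were the library scaling factor as a covariate and leaving out together the 4 libraries that lay apart from their group on the first principal component. The groups share replicate numbers, but the labels do not say that a number marks a shared culture or day. Deviations of same-numbered libraries from their group means correlated over mRNA genes at -0.37 to 0.60 (30 pairs, median 0.16). Those of libraries with different numbers correlated at -0.62 to 0.48 (60 pairs, median -0.11). All 3 same-numbered pairs lay above 0.1 in 3 of 10 pairs of groups: silver ion with Ag-Cit80 (0.27 to 0.30), silver ion with Ag-PVP80 (0.16 to 0.29) and Ag-Cit80 with Ag-PVP80 (0.13 to 0.60). For these the numbers were taken as a pairing that comes from the data and not from the labels, and the fit with the number as a block, over all 5 groups, is given beside a count that it moves by over 1.5 times. This reading was adopted after the calls of both fits had been seen. Principal components were taken from the centred log2 values of the tested mRNA genes. Shares of variance between groups were tested with 100000 permutations of the group labels. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.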

Results

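Tetrahymena thermophila is a free-living ciliate, a single-celled organism used in toxicology. RNA of strain SB210, kept in SSP medium, was sequenced after 24 h with one of 4 forms of silver and from untreated cells. The 5 groups were an untreated control, silver ion (silver nitrate) and 3 kinds of nanoparticle, called Ag-Cit10, Ag-Cit80 and Ag-PVP80, with 3 libraries each. Each form was given at its own 24 h IC50, so the groups were not matched in silver concentration, and the concentrations are not given in the sources used here. The labels do not spell out what the nanoparticle names stand for. They also do not say that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. One table held 23401 mRNA genes and another held 5863 lncRNAs (long non-coding RNAs), both in FPKM. After the filter, 12588 mRNA genes and 1779 lncRNAs were tested. The mRNA values summed to between 743781 and 798001 FPKM per library. Read totals are not given in the sources used here, so the counting error behind each value is unknown.

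The libraries of a group did not always lie together. On the first principal component of the mRNA values, 45.6% of the variance, control replicate 1, Ag-Cit10 replicate 1, Ag-Cit80 replicate 3 and Ag-PVP80 replicate 2 each lay on the other side of 0 from the rest of their group. Differences between the 5 groups made up 36.7% of the variance on this component (one-sided permutation p = 0.27; adjusted p = 0.32 over 7 such tests). On the second component, 14.3% of the variance, group differences made up 89.4% (one-sided permutation p = 0.00026, adjusted p = 0.0018). The control scores of 0.318 to 0.476 and the Ag-PVP80 scores of -0.391 to -0.302 lay clear of the rest there, while Ag-Cit10 overlapped with silver ion and with Ag-Cit80. Over all tested genes the groups held 40.98% of the variance for mRNA and 37.3% for lncRNA (adjusted permutation p = 0.11 each), and 41.7% and 37.9% after median-of-ratios scaling (adjusted permutation p = 0.065 and 0.063), and none of these passed 0.05. One lncRNA, LXLOC_024369, made up 22.6% to 29.8% of all FPKM in a library. It was listed at 284040 ± 2311 FPKM with silver ion, 318970 ± 31173 in the control, 345135 ± 35459 with Ag-Cit10, 352029 ± 43725 with Ag-Cit80 and 312800 ± 64326 with Ag-PVP80 (SD, n = 3 each). Every pair of libraries correlated across genes at a Pearson r of 0.968 to 0.994, and no 2 libraries held identical values.

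**Figure D1:**
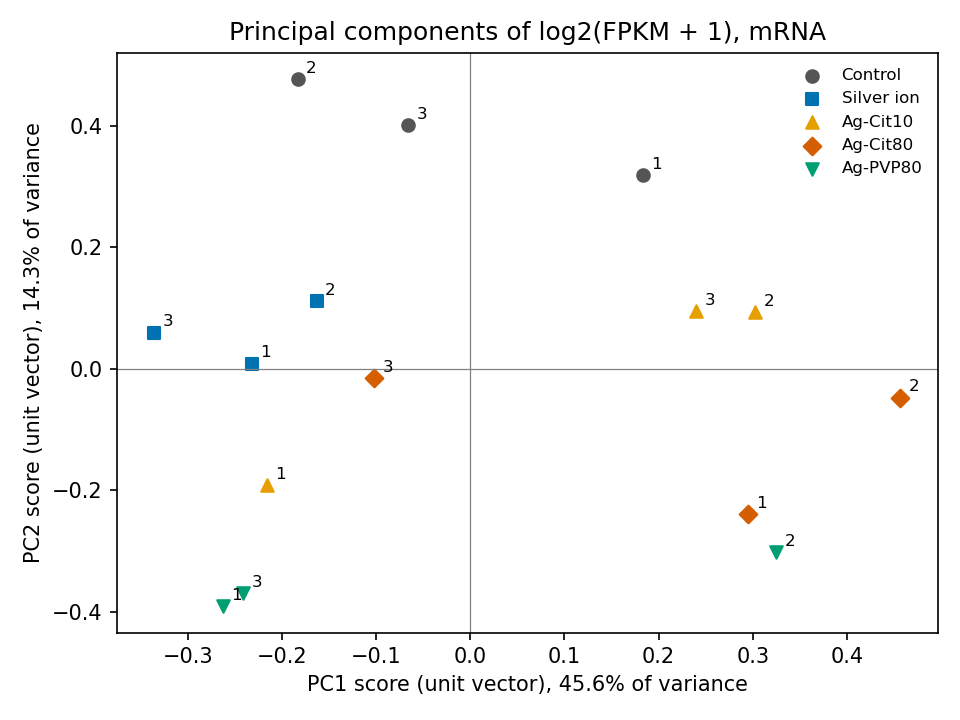
Scores of the 15 libraries on the first and second principal components of log2(FPKM + 1) over 12588 mRNA genes, with the share of variance on each axis; symbols mark the group and digits the replicate. Control, Ag-Cit10, Ag-Cit80 and Ag-PVP80 each have 1 library on the other side of 0 on the first axis, while the second axis runs from the control libraries at the top to the Ag-PVP80 libraries at the bottom.

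Silver ion was compared with the control to find transcripts that differ after exposure to dissolved silver. TTHERM_00660230 rose from 9.06 ± 1.61 FPKM in the control to 1272 ± 62.8 with silver ion, a log2 change of 6.99 (SE 0.14; SD over n = 3 per group). TTHERM_00241640 rose from 15.3 ± 1.19 to 316 ± 25.5 FPKM, a log2 change of 4.28 (SE 0.09). TTHERM_00467520 fell from 65.0 ± 4.75 to 21.8 ± 6.31 FPKM, and TTHERM_00284090 fell from 7.89 ± 3.30 to 1.92 ± 0.706 FPKM. In limma the adjusted p was 5.04e-13 for TTHERM_00660230, 1.42e-12 for TTHERM_00241640, 0.00311 for TTHERM_00467520 and 0.0323 for TTHERM_00284090, and all 3 silver libraries lay on one side of all 3 controls for each. limma called 35 of 12588 mRNA genes at an adjusted p under 0.05, 15 higher and 20 lower, of which 17 changed at least 2-fold. The count was 14 without control replicate 2, 10 without control replicate 3 and 15, 18 and 12 without silver ion replicates 1, 2 and 3, and median-of-ratios scaling gave 13 higher and 69 lower, 15.9% higher against 42.9%. With only the 2 groups in the fit the count was 121, 62 higher and 59 lower. With the scaling factor as a covariate it was 129, 37 higher and 92 lower. TTHERM_00284090 did not pass limma's test without control replicate 2 or 3 or silver ion replicate 1 or 3, with a pseudocount of 0.1 or with no filter on low values (adjusted p = 0.0767 to 0.186 in these settings).

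Ag-Cit10 was compared with the control in the same way. TTHERM_00660230 rose from 9.06 ± 1.61 to 5908 ± 1006 FPKM, a log2 change of 9.20 (SE 0.14), and TTHERM_00241640 rose from 15.3 ± 1.19 to 1071 ± 69.2 FPKM, a log2 change of 6.04 (SE 0.09; SD over n = 3 per group). TTHERM_00379080 fell from 4.63 ± 0.688 to 0.62 ± 0.181 FPKM and TTHERM_00979810 from 3.39 ± 0.907 to 1.01 ± 0.360 FPKM. Their adjusted p in limma was 1.18e-14, 1.28e-14, 3.86e-05 and 0.0336 in that order, with no overlap between the 3 treated and the 3 control values of any of them. limma called 74 mRNA genes at an adjusted p under 0.05, 32 higher and 42 lower, of which 14 changed at least 2-fold. In the single simulated draw for this comparison limma called 52 unchanged genes at an adjusted p under 0.05, against 9, 0 and 2 in those for silver ion, Ag-Cit80 and Ag-PVP80. Each draw used the residuals of all libraries, so the 52 is no property of Ag-Cit10 and gives no rate of false calls among its 74. The count was 309 without Ag-Cit10 replicate 1, 33 and 20 without Ag-Cit10 replicates 2 and 3 and 44, 24 and 28 without control replicates 1, 2 and 3, while scaling gave 38 higher and 22 lower, 63.3% higher against 43.2%. With only the 2 groups in the fit the count was 9, 8 higher and 1 lower. With the scaling factor as a covariate it was 307, 168 higher and 139 lower. TTHERM_00979810 did not pass limma's test in 7 of its alternatives (adjusted p = 0.0574 to 0.216 in these), among them those without control replicate 2 or 3 or Ag-Cit10 replicate 2 or 3.

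With Ag-Cit80, TTHERM_00660230 reached 6427 ± 496 FPKM against 9.06 ± 1.61 in the control, a log2 change of 9.33 (SE 0.14), and TTHERM_00241640 reached 1222 ± 90.4 FPKM against 15.3 ± 1.19, a log2 change of 6.23 (SE 0.09; SD over n = 3 per group). TTHERM_00784250 fell from 66.9 ± 19.2 to 11.6 ± 4.75 FPKM and TTHERM_00284090 from 7.89 ± 3.30 to 0.77 ± 0.466 FPKM. In limma the adjusted p was 8.4e-15 for both genes that rose, 0.000348 for TTHERM_00784250 and 0.000563 for TTHERM_00284090, and the 3 treated values lay clear of the 3 controls for each. The genes called by limma at an adjusted p under 0.05 numbered 305, with 65 higher and 240 lower, and 70 of them changed at least 2-fold. This count was 97 and 110 without control replicates 2 and 3, 143 and 118 without Ag-Cit80 replicates 1 and 2 and 461 without Ag-Cit80 replicate 3. With only the 2 groups in the fit it was 92, 28 higher and 64 lower. With the scaling factor as a covariate it was 468, 189 higher and 279 lower.

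With Ag-PVP80, TTHERM_00660230 reached 5862 ± 625 FPKM, a log2 change from the control of 9.19 (SE 0.14), and TTHERM_00241640 reached 1120 ± 95.7 FPKM, a log2 change of 6.10 (SE 0.09; SD over n = 3 per group). TTHERM_00784250 fell from 66.9 ± 19.2 to 8.09 ± 0.245 FPKM and TTHERM_00284090 from 7.89 ± 3.30 to 0.427 ± 0.0987 FPKM. The adjusted p in limma was 1.11e-14 for both genes that rose, 6.31e-05 for TTHERM_00784250 and 0.00014 for TTHERM_00284090, again with no overlap between treated and control values. limma called 687 genes at an adjusted p under 0.05, 130 higher and 557 lower, of which 111 changed at least 2-fold. The count was 298 and 317 without control replicates 2 and 3 and 418 and 367 without Ag-PVP80 replicates 1 and 3, and scaling gave 299 higher and 460 lower, 39.4% higher against 18.9%. With only the 2 groups in the fit the count was 315, 75 higher and 240 lower. With the scaling factor as a covariate it was 2305, 1110 higher and 1195 lower.

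**Figure D2:**
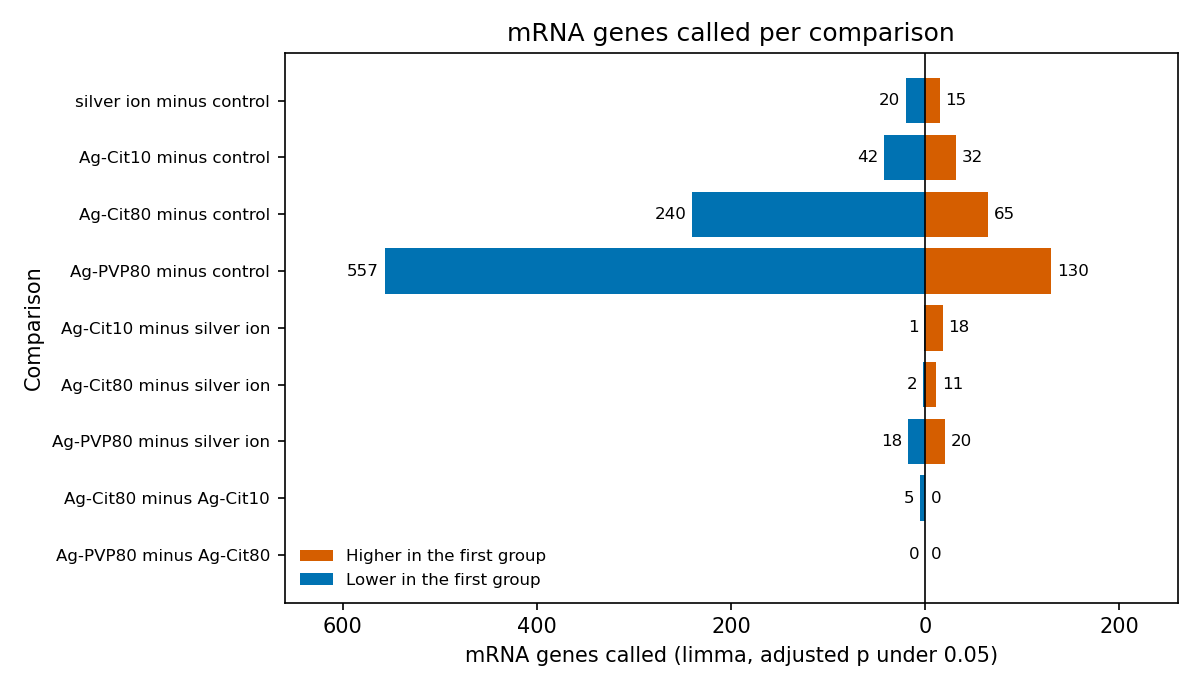
Number of mRNA genes called by limma at an adjusted p under 0.05 in each of 9 comparisons; bars to the right count genes higher in the group named first and bars to the left genes lower in it. Ag-PVP80 against the control has the longest bars with 130 higher and 557 lower genes, and Ag-PVP80 against Ag-Cit80 has none.

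Values of 3 against 3 libraries do not overlap for 10% of genes by chance. They did not overlap for 26.1% of tested mRNA genes between silver ion and control, 12.1% for Ag-Cit10, 17.3% for Ag-Cit80 and 22.3% for Ag-PVP80. Because genes shift together between libraries, such a share can move either way from 10% without many genes called. It was 30.1% between Ag-Cit80 and silver ion, where 13 genes were called, and 4.77% between Ag-Cit80 and Ag-Cit10. The number of genes called was not tested for a difference between the forms of silver. The median log2 change over all tested genes was 0.10 for silver ion, -0.07 for Ag-Cit10, -0.11 for Ag-Cit80 and -0.03 for Ag-PVP80 against the control, and -0.17, -0.23 and -0.15 for the 3 nanoparticles in the same order against silver ion. Median-of-ratios scaling, which evens out such medians by construction, brought each of them to between -0.01 and 0.02.

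A set of 21 mRNA genes was called in the same direction with all 4 forms of silver, 13 higher and 8 lower. TTHERM_00660230 and TTHERM_00241640 led the risers. Of 6 genes chosen after their values were seen, 4 were among the 13, namely TTHERM_00241650, TTHERM_000440549, MXLOC_008985 and TTHERM_00433530. TTHERM_00241650 stood at 1.03 ± 0.168 FPKM in the control, 5.55 ± 1.85 with silver ion, 17.2 ± 8.44 with Ag-Cit10, 18.6 ± 6.76 with Ag-Cit80 and 17.6 ± 1.41 with Ag-PVP80. TTHERM_000440549 stood at 1.21 ± 0.530, 7.03 ± 1.76, 18.8 ± 7.43, 14.4 ± 3.73 and 23.6 ± 6.13 FPKM in the same order (SD, n = 3 each). TTHERM_00379080 was among the 8 fallers, from 4.63 ± 0.688 FPKM in the control to 0.96 ± 0.208 with silver ion, 0.62 ± 0.181 with Ag-Cit10, 0.19 ± 0.252 with Ag-Cit80 and 0.07 ± 0.0625 with Ag-PVP80. Independent lists of these lengths would share 2.03e-06 higher and 5.63e-05 lower genes, and 100 simulations of unchanged groups against shared controls gave a mean and a maximum of 0. The simulated groups held no true change, so their lists did not have the lengths of the real ones. Their result does not show how many genes shared controls would add between the real lists. The 3 controls cannot be split into parts of 2 libraries, so part of the excess may come from the shared controls. No gene was called higher with one form and lower with another. The count was 8 without control replicate 2 and 5 without control replicate 3, and some calls with silver ion depended on 1 library. In limma TTHERM_00241650 had an adjusted p of 0.106 to 0.168 without any 1 control or silver ion replicate 1 or 2, TTHERM_000440549 of 0.0513 to 0.109 without control replicate 1 or 3 or silver ion replicate 1 or 3, and TTHERM_00433530 of 0.116 to 0.186 without control replicate 2 or 3 or silver ion replicate 1 or 2. With silver ion, TTHERM_00433530 also missed limma's threshold after scaling (adjusted p = 0.193), and with no filter on low values TTHERM_00433530 and TTHERM_00241650 both missed it (adjusted p = 0.0655 and 0.0767).

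Across 12588 genes the log2 changes of 2 comparisons with the control correlated at a Pearson r of 0.740 for silver ion and Ag-PVP80, 0.784 for Ag-Cit10 and Ag-Cit80, 0.670 for Ag-Cit10 and Ag-PVP80 and 0.634 for Ag-Cit80 and Ag-PVP80. Simulated unchanged groups gave a mean r of 0.490, 0.483, 0.493 and 0.449 for these pairs. The covariances were 0.0641, 0.0595, 0.0573 and 0.0615, against simulated means of 0.0201, 0.0216, 0.0207 and 0.0191. For silver ion with Ag-Cit10 the r was 0.486 against a simulated 0.523, and for silver ion with Ag-Cit80 it was 0.432 against 0.477, with covariances of 0.0330 against 0.0220 and 0.0332 against 0.0198. Of 100 simulations, 2, 5, 6 and 4 reached the covariance of the first 4 pairs, and 21 and 22 that of the last 2. Genes are not independent replicates, and the simulations ran from an r of -0.561 to 0.917. Of the 35 genes called with silver ion, 14 of the 15 higher and all 20 lower were also called with Ag-PVP80, where independent lists would share 0.155 and 0.885 genes and the simulations 0. Shared counts from simulations without a true change do not show the overlap to be had between lists of the real lengths. Silver ion shared 13 higher and 8 lower genes with Ag-Cit10 and 14 and 19 with Ag-Cit80, where the simulations shared on average 2.83 and 5.25, and 2.28 and 4.7 genes, with up to 525 and 470 lower genes in a single simulation.

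The nanoparticles were compared with silver ion directly to find transcripts that differ between particulate and dissolved silver. TTHERM_00433530 stood at 1.89 ± 0.402 FPKM in the control and 4.70 ± 1.15 with silver ion, and at 72.1 ± 11.1 with Ag-Cit10, 78.4 ± 12.3 with Ag-Cit80 and 66.0 ± 9.83 with Ag-PVP80 (SD, n = 3 each). MXLOC_008985, which has no locus tag, stood at 18.2 ± 2.14, 46.8 ± 7.19, 447 ± 99.02, 519 ± 59.9 and 424 ± 59.5 FPKM in the same order. TTHERM_00660230 was higher with each nanoparticle than with silver ion by a log2 change of 2.20 with Ag-Cit10, 2.33 with Ag-Cit80 and 2.20 with Ag-PVP80, and TTHERM_00241640 by 1.76, 1.95 and 1.82. TTHERM_00320090 was lower with nanoparticles, at 18.9 ± 1.98, 18.9 ± 0.248 and 16.6 ± 1.19 FPKM against 30.9 ± 2.16 with silver ion. For TTHERM_00433530 limma gave an adjusted p of 8.18e-08, 4.29e-08 and 1.29e-07 in the 3 comparisons and for MXLOC_008985 1.64e-07, 4.29e-08 and 1.39e-07, with every nanoparticle library above every silver ion library.

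**Figure D3:**
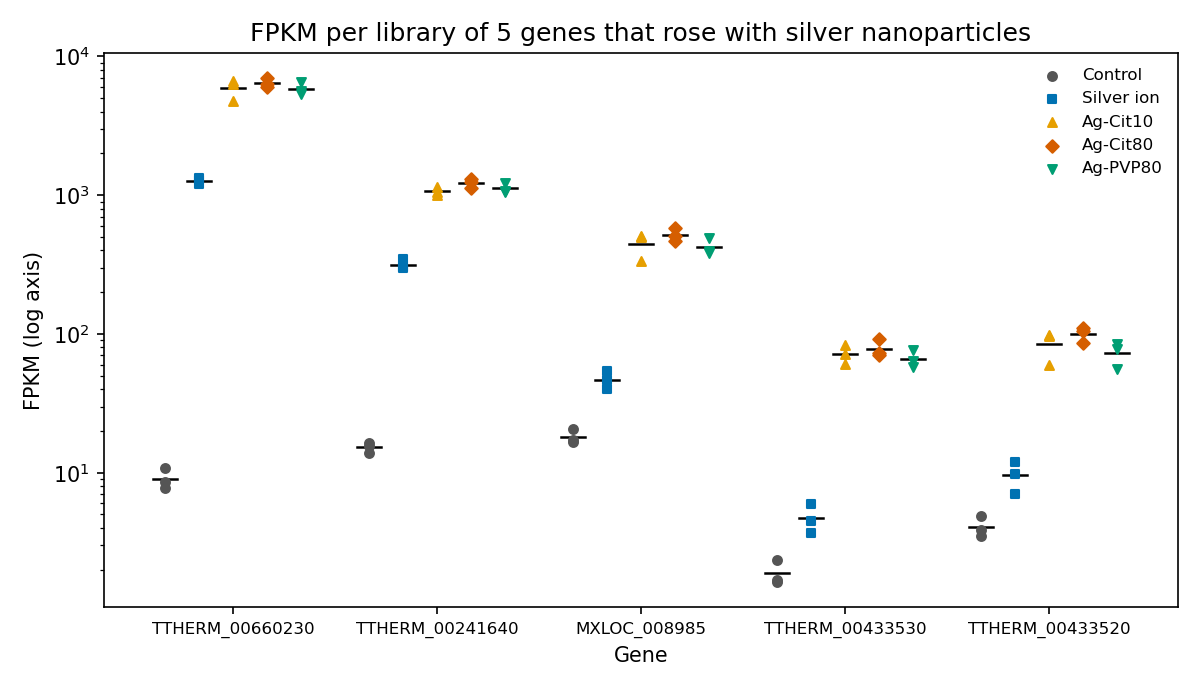
FPKM of 5 genes on a log axis, 1 symbol per library and a bar at the mean of each group of 3 libraries. All 9 nanoparticle libraries lie above the 3 silver ion libraries for each gene, as for MXLOC_008985 with group means of 424 to 519 FPKM against 46.8 FPKM.

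Of the genes chosen after their values were seen, TTHERM_00433520 and TTHERM_00529930 also differed between nanoparticles and silver ion. TTHERM_00433520 stood at 4.07 ± 0.720 FPKM in the control, 9.58 ± 2.46 with silver ion, 85.1 ± 22.2 with Ag-Cit10, 100.3 ± 13.2 with Ag-Cit80 and 72.8 ± 14.6 with Ag-PVP80, and its difference between silver ion and control did not pass limma's test (log2 change 1.04, adjusted p = 0.0792). It passed with the replicate block (limma adjusted p = 0.0481), with only the 2 groups in the fit (0.0458), with the scaling factor as a covariate (0.0245) and without the 4 libraries that lay apart (0.0238), at log2 changes of 1.04 to 1.19. The last of these settings narrows the spread by construction, so it lends no weight. TTHERM_00529930 was listed at 0 in the 3 controls and in 2 silver ion libraries and at 0.01 FPKM in the third, and between 2.56 and 4.72 FPKM in the 9 nanoparticle libraries. In limma its adjusted p against silver ion was 9.94e-07 for Ag-Cit10, 6.47e-06 for Ag-Cit80 and 1.52e-05 for Ag-PVP80. An exact 0 can be a failed estimate, so no fold is given. TTHERM_000440549 and TTHERM_00241650 did not pass limma's test between silver ion and Ag-Cit10 (adjusted p = 0.191 and 0.125) or Ag-Cit80 (0.187 and 0.101). They passed it between silver ion and Ag-PVP80 (limma adjusted p = 0.0336 and 0.0496), but TTHERM_000440549 had an adjusted p in limma of 0.115 to 0.177 without any 1 silver ion library or Ag-PVP80 replicate 1 or 3, and TTHERM_00241650 one of 0.112 to 0.238 without any 1 library of the 2 groups. With no filter on low values these 2 calls were lost as well (limma adjusted p = 0.0673 and 0.0839), as they were with only the 2 groups in the fit (0.103 and 0.0973), and that of TTHERM_000440549 with a pseudocount of 0.1 (0.0538). Some alternatives did call them with the other nanoparticles: scaling called both with Ag-Cit10 (limma adjusted p = 0.00835 and 0.0374) and TTHERM_00241650 with Ag-Cit80 (0.0468). The covariate called TTHERM_000440549 with both (limma adjusted p = 0.00209 and 0.0167), and TTHERM_00241650 passed with Ag-Cit80 under the replicate block (0.0487) and without Ag-Cit80 replicate 3 (0.0316). Both also passed with both once the 4 libraries that lay apart were left out (limma adjusted p of 0.00129 to 0.0148). These libraries were picked from their expression values, which narrows the spread by construction, so these calls lend no weight.

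Together 7 genes were higher and 1 was lower in all 3 comparisons of a nanoparticle with silver ion, the 7 including the 6 risers named for these comparisons and the 1 being TTHERM_00320090. limma called 19 genes between Ag-Cit10 and silver ion, 18 higher and 1 lower, 13 between Ag-Cit80 and silver ion, 11 higher and 2 lower, and 38 between Ag-PVP80 and silver ion, 20 higher and 18 lower, at an adjusted p under 0.05. The other gene lower with Ag-Cit80 was TTHERM_00726110, at 0.357 ± 0.291 against 2.35 ± 0.507 FPKM, and the largest falls with Ag-PVP80 were TTHERM_00784250, at 8.09 ± 0.245 against 30.4 ± 5.11 FPKM, and TTHERM_00146250, at 5.09 ± 0.0404 against 11.5 ± 2.06 FPKM. TTHERM_00726110 was low throughout, at 0.867 ± 0.306 FPKM in the control, 0.783 ± 0.414 with Ag-Cit10 and 1.02 ± 0.330 with Ag-PVP80. Its mean with silver ion thus also lay above that of the control. Without Ag-Cit80 replicate 3, limma called 2389 genes between Ag-Cit80 and silver ion, 87 higher and 2302 lower, and without Ag-Cit10 replicate 1 it called 168 between Ag-Cit10 and silver ion, 41 higher and 127 lower. Between Ag-Cit80 and silver ion the count was 7 without silver ion replicate 2 or Ag-Cit80 replicate 1 or 2, and between Ag-Cit10 and silver ion it was 11 without silver ion replicate 1 or Ag-Cit10 replicate 3 and 12 without silver ion replicate 2 or 3. Between Ag-PVP80 and silver ion it was 10, 9 and 10 without silver ion replicates 1, 2 and 3 and 11, 15 and 12 without Ag-PVP80 replicates 1, 2 and 3. The adjusted p in limma of TTHERM_00784250 was 0.0501 to 0.119 without any 1 library of the 2 groups, that of TTHERM_00146250 0.0832 to 0.142 without silver ion replicate 2 or 3 or any Ag-PVP80 library, and that of TTHERM_00726110 0.131 to 0.182 without silver ion replicate 2 or 3 or Ag-Cit80 replicate 1 or 2. For TTHERM_00320090 limma's adjusted p was 0.0505 to 0.0759 with Ag-Cit10 without silver ion replicate 1 or 2 or Ag-Cit10 replicate 3, and 0.0601 to 0.143 with Ag-Cit80 without silver ion replicate 1 or 2 or Ag-Cit80 replicate 1 or 2; with scaling it was 0.425 and 0.261, and with only the 2 groups in the fit 0.118 and 0.109. With only the 2 groups in the fit limma also gave TTHERM_00146250 an adjusted p of 0.0987 and TTHERM_00726110 one of 0.0983, and TTHERM_00726110 had 0.0968 with a pseudocount of 0.1, 0.0547 with no filter on low values and 0.33 with the covariate. Scaling gave 38 higher and 6 lower genes between Ag-PVP80 and silver ion, 86.4% higher against 52.6%, while the replicate number as a block gave 29 higher and 57 lower, 33.7% higher.

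The nanoparticles were also compared with one another, each at its own IC50 and so at unmatched concentrations. Between Ag-Cit80 and Ag-Cit10, which share the first part of their name, TTHERM_01021930 was lower with Ag-Cit80, at 34.1 ± 10.4 against 106.6 ± 14.1 FPKM, and TTHERM_00070750 at 15.4 ± 2.26 against 42.7 ± 6.08 FPKM (SD, n = 3 each). Both were higher in the control than with Ag-Cit80, at 105.8 ± 33.6 and 58.1 ± 17.1 FPKM. limma gave each an adjusted p of 0.0323 and called 5 genes in all, all of them lower with Ag-Cit80; the other 3, named after their values were seen, were TTHERM_000770889, TTHERM_01284760 and TTHERM_00143800. No gene was called once any 1 library of the 2 groups was left out, when TTHERM_01021930 and TTHERM_00070750 had an adjusted p in limma of 0.0516 to 0.248. These 2 genes also missed limma's threshold with no filter on low values (adjusted p = 0.0871 and 0.081) and with only the 2 groups in the fit (0.163 and 0.139). Between Ag-PVP80 and Ag-Cit80, which share the number in their name, limma called 0 genes, with 1172 at an unadjusted p under 0.05. TTHERM_00660230 and TTHERM_00241640 differed little between these forms, at 5862 ± 625 against 6427 ± 496 FPKM and 1120 ± 95.7 against 1222 ± 90.4 FPKM. The 95% interval of the log2 difference between Ag-PVP80 and Ag-Cit80 was -0.65 to 0.07 for MXLOC_008985 and -0.62 to 0.13 for TTHERM_00433530. Scaling gave 35 genes between Ag-PVP80 and Ag-Cit80, 5 higher and 30 lower.

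Among lncRNAs, LXLOC_013553 rose with all 3 nanoparticles, from 0.0233 ± 0.0404 FPKM in the control to 1.62 ± 0.0208 with Ag-Cit10, 1.79 ± 0.522 with Ag-Cit80 and 1.77 ± 0.184 with Ag-PVP80 (SD, n = 3 each; limma adjusted p = 0.0011, 0.000567 and 0.000279). It stood at 0.57 ± 0.269 FPKM with silver ion. LXLOC_014336 was listed at 0 in the 3 controls and at 8.18 to 16.9 FPKM with silver ion and 5 to 9.96 FPKM with Ag-Cit80, which limma called at an adjusted p of 0.0126 and 0.0144. It was listed at 2.42 to 3.39 FPKM with Ag-Cit10 and 0 to 5.48 FPKM with Ag-PVP80. LXLOC_013524 rose with silver ion from 104.8 ± 2.56 to 146.3 ± 10.99 FPKM (limma adjusted p = 0.0433), but its 15 values are those of the mRNA gene TTHERM_00663790, and whether the 2 entries are one transcript was not tested. LXLOC_013524 stood at 141.0 ± 9.48 FPKM with Ag-Cit10, 133.6 ± 3.71 with Ag-Cit80 and 172.9 ± 8.92 with Ag-PVP80. LXLOC_022497 and LXLOC_007527 rose with Ag-Cit10, to 31.5 ± 5.41 from 16.2 ± 2.11 FPKM and to 830 ± 80.19 from 521 ± 36.8 FPKM. The other nanoparticles gave like levels. LXLOC_022497 stood at 30.2 ± 2.42 FPKM with Ag-Cit80, 30.2 ± 3.71 with Ag-PVP80 and 18.3 ± 1.56 with silver ion. LXLOC_007527 stood at 827 ± 83.4, 866 ± 57.4 and 688 ± 41.2 FPKM in the same order. LXLOC_024877 fell from 7.40 ± 2.94 FPKM to 0.99 ± 0.668 with Ag-Cit80 and 0.683 ± 0.332 with Ag-PVP80, and LXLOC_027733 fell from 21.8 ± 1.80 FPKM to 11.5 ± 1.86 with Ag-Cit10 and 6.59 ± 0.846 with Ag-PVP80. LXLOC_024877 stood at 2.35 ± 0.630 FPKM with silver ion and 4.99 ± 0.552 with Ag-Cit10. LXLOC_027733 stood at 13.4 ± 1.84 FPKM with silver ion and 9.61 ± 1.56 with Ag-Cit80. LXLOC_015451 rose with Ag-PVP80 to 3.29 ± 0.638 from 0.59 ± 0.144 FPKM. It stood at 1.88 ± 0.0513 FPKM with silver ion, 1.59 ± 0.467 with Ag-Cit10 and 1.75 ± 0.493 with Ag-Cit80.

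limma called 2 of 1779 lncRNAs with silver ion, both higher, 12 with Ag-Cit10, 7 higher and 5 lower, 25 with Ag-Cit80, 10 higher and 15 lower, and 39 with Ag-PVP80, 21 higher and 18 lower, against the control at an adjusted p under 0.05. Between Ag-PVP80 and silver ion 6 lncRNAs were called, 2 higher and 4 lower. limma called 0 lncRNAs between silver ion and Ag-Cit10, silver ion and Ag-Cit80, Ag-Cit10 and Ag-Cit80 or Ag-Cit80 and Ag-PVP80, with 212, 350, 66 and 157 at an unadjusted p under 0.05. The replicate block gave 1 lncRNA between Ag-Cit80 and silver ion. With scaling the higher and lower calls were 1 and 1 for silver ion, 6 and 0 for Ag-Cit10 and 51 and 28 for Ag-PVP80 against the control, and 0 between Ag-PVP80 and silver ion. Without control replicate 2 or 3, or silver ion replicate 1 or 3, limma called 0 lncRNAs with silver ion, and LXLOC_014336 then had an adjusted p in limma of 0.0607 to 0.0865; LXLOC_013524 had one of 0.108 to 0.232 in these settings and without control replicate 1, and of 0.455 with scaling, 0.16 with no filter on low values and 0.067 with only the 2 groups in the fit. With Ag-Cit80, LXLOC_014336 had an adjusted p in limma of 0.0512 to 0.0748 without control replicate 2 or 3 or Ag-Cit80 replicate 1 or 2. With Ag-Cit10, limma's adjusted p was 0.0574 for LXLOC_022497 and LXLOC_007527 without control replicate 1 and 0.0751 and 0.0633 without Ag-Cit10 replicate 3, and it was 0.0574 to 0.141 for LXLOC_027733 without any 1 control or Ag-Cit10 replicate 3. LXLOC_027733 also lost its Ag-Cit10 call with scaling (limma adjusted p = 0.0793) and with no filter on low values (0.0647). With only the 2 groups in the fit limma's adjusted p with Ag-Cit10 was 0.0992 for LXLOC_027733, 0.127 for LXLOC_022497 and 0.0674 for LXLOC_007527, and with Ag-Cit80 it was 0.0521 for LXLOC_024877. The Ag-Cit10 count was 1 without control replicate 1 or Ag-Cit10 replicate 3, 3 without control replicate 2 and 6 without control replicate 3, and against silver ion limma called 9 lncRNAs with Ag-Cit10 without Ag-Cit10 replicate 1 and 82 with Ag-Cit80 without Ag-Cit80 replicate 3. Between Ag-PVP80 and silver ion the count was 0 without any 1 silver ion library or Ag-PVP80 replicate 3, and 1 and 2 without Ag-PVP80 replicates 1 and 2. For Ag-Cit80 the count was 5 and 7 without control replicates 2 and 3 and 6 and 9 without Ag-Cit80 replicates 1 and 2, and for Ag-PVP80 it was 25, 19 and 22 without control replicates 1, 2 and 3 and 25 without Ag-PVP80 replicate 3.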

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

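The covariate, the joint removal of 4 libraries and every setting for the correlations and for the genes differing between each nanoparticle and silver ion were chosen after seeing the data; the other alternatives were planned. No named gene's call turned to the opposite sign. The balance of higher against lower calls did turn over, in 16 of 104 alternative mRNA counts and 15 of 65 lncRNA counts, leaving aside comparisons with no call to begin with. For mRNA this held in 7 of 13 settings for Ag-Cit10 against control, in 4 for Ag-PVP80, 2 for Ag-Cit10 and 2 for Ag-Cit80 against silver ion and in 1 for silver ion against control. For lncRNAs it held in 6 settings for Ag-Cit80, 2 for Ag-Cit10, 2 for silver ion and 1 for Ag-PVP80 against control and in 4 for Ag-PVP80 against silver ion. Of the values of named genes under the alternatives, 1087 kept their side of the threshold, 235 lost the call and 17 gained it, and the 6 correlations of log2 changes kept their sign. Without the 4 libraries, the r fell to 0.234 for Ag-Cit10 with Ag-PVP80, 0.325 for Ag-Cit80 with Ag-PVP80, 0.288 for silver ion with Ag-Cit10 and 0.336 for silver ion with Ag-Cit80, below the means of 0.449 to 0.523 simulated with all 15 libraries. With the covariate it was 0.694 for silver ion with Ag-Cit80 and 0.630 for silver ion with Ag-Cit10. The cause of the moves listed here was not tested unless stated. The 3 libraries per group and the unknown depth limit what can be told. The tests of gene lists and product families and their alternatives were not run, since no list matched a gene.

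With median-of-ratios scaling the mRNA counts were 82 for silver ion against control, 49 for Ag-Cit10 against silver ion, 20 for Ag-Cit80 against Ag-Cit10 and 35 for Ag-PVP80 against Ag-Cit80. The lncRNA counts were 6 for Ag-Cit10 and 79 for Ag-PVP80 against control, 6 for Ag-Cit10 and 0 for Ag-PVP80 against silver ion, and 2 each for Ag-Cit80 against Ag-Cit10 and Ag-PVP80 against Ag-Cit80. With no filter on low values, so that more genes were tested, the mRNA counts were 21 for silver ion against control, 8 for Ag-Cit80 against silver ion and 3 for Ag-Cit80 against Ag-Cit10, and 13 genes changed the same way with all 4 forms. The lncRNA counts were then 1, 3, 9 and 24 for silver ion, Ag-Cit10, Ag-Cit80 and Ag-PVP80 against control and 0 for Ag-PVP80 against silver ion. With a pseudocount of 0.1 the lncRNA counts were 4 for silver ion against control and 2 for Ag-PVP80 against silver ion. 

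With only the 2 groups compared in the fit, and so fewer samples, the mRNA counts against control were 121 for silver ion, 9 for Ag-Cit10, 92 for Ag-Cit80 and 315 for Ag-PVP80. Against silver ion they were 10, 8 and 13 for the nanoparticles in that order, with 0 for Ag-Cit80 against Ag-Cit10 and 1 for Ag-PVP80 against Ag-Cit80. The lncRNA counts were 2, 7 and 18 for the nanoparticles against control, 3, 1 and 0 against silver ion and 1 for Ag-Cit80 against Ag-Cit10. With the scaling factor as a covariate the mRNA counts against control were 129, 307, 468 and 2305 for silver ion, Ag-Cit10, Ag-Cit80 and Ag-PVP80, of which 28.7%, 54.7%, 40.4% and 48.2% were higher, against 42.9%, 43.2%, 21.3% and 18.9% without it. They were 59 and 203 for Ag-Cit10 and Ag-PVP80 against silver ion, 17 for Ag-Cit80 against Ag-Cit10 and 104 for Ag-PVP80 against Ag-Cit80, and 66 genes changed the same way with all 4 forms. The lncRNA counts were 8, 31, 54 and 216 against control, 32 for Ag-PVP80 against silver ion, 1 for Ag-Cit80 against Ag-Cit10 and 2 for Ag-PVP80 against Ag-Cit80. The factors come from the same mRNA values and run along the first principal component. Ag-Cit80 replicate 2 had a factor of 0.835 at a score of 0.457, and silver ion replicate 3 one of 1.21 at -0.336. The covariate thus takes up spread within groups, so its counts are no plain measure of a treatment effect.

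The 4 libraries left out together were picked from their expression values, which by construction narrows the spread within groups and leaves groups on different sides of the first principal component. Counts from this setting are therefore no measure of a treatment effect. They were 205, 2266, 4467 and 1633 mRNA genes for silver ion, Ag-Cit10, Ag-Cit80 and Ag-PVP80 against control, 4407, 6374 and 250 for the nanoparticles against silver ion, 69 for Ag-Cit80 against Ag-Cit10 and 5056 for Ag-PVP80 against Ag-Cit80. The lncRNA counts were 14, 114, 313 and 90 against control, 387, 576 and 3 against silver ion, 13 for Ag-Cit80 against Ag-Cit10 and 481 for Ag-PVP80 against Ag-Cit80. The setting gave 100 genes changed the same way with all 4 forms and 60 differing the same way between each nanoparticle and silver ion. 

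Leaving out 1 library at a time gave 10 to 32 mRNA genes for silver ion, 20 to 309 for Ag-Cit10, 97 to 461 for Ag-Cit80 and 298 to 578 for Ag-PVP80 against control. Against silver ion the ranges were 11 to 168, 7 to 2389 and 9 to 15 for the nanoparticles, with 0 in each case for Ag-Cit80 against Ag-Cit10. For lncRNAs they were 0 to 3, 1 to 15, 5 to 28 and 19 to 37 against control and 0 to 9, 0 to 82 and 0 to 2 against silver ion. Without 1 control, 5 to 16 genes changed the same way with all 4 forms.

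The replicate numbers met the check for a pairing in 3 of 10 pairs of groups and in none with the control. As a hint from the data, 12 of 15 libraries lay closest to their own number, and 19 of 30 same-numbered pairs correlated above 0.1. So did 18 of 60 pairs with different numbers, at an r of up to 0.478. With the replicate block the mRNA counts were 79 for silver ion and 115 for Ag-Cit10 against control, 86 for Ag-PVP80 against silver ion (29 higher, 57 lower) and 8 for Ag-Cit80 against Ag-Cit10, and 48 genes changed the same way with all 4 forms. The lncRNA counts under the block were 8 for silver ion against control and 1 each for Ag-Cit10 against silver ion, Ag-Cit80 against silver ion and Ag-Cit80 against Ag-Cit10. Among named genes in the 3 pairs of groups that met the check, the block gave TTHERM_00241650 a call between Ag-Cit80 and silver ion (limma adjusted p = 0.0487), took that of LXLOC_006060 between Ag-PVP80 and silver ion (limma adjusted p = 0.0589) and that of TTHERM_00467520 between Ag-Cit80 and silver ion (limma adjusted p = 0.0607), and changed no other call.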

Other observations

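The tests of neighbouring genes, the counts of genes by length and the tests of the dominant transcript, of depth, of scaling and of the genes called between Ag-PVP80 and control, were chosen only after the result was seen. Some genes that rose with silver sit next to each other in the reference assembly JCVI-TTA1-2.2. TTHERM_00241640 and TTHERM_00241650 are neighbours and were both called higher with all 4 forms of silver, and TTHERM_00433530 and TTHERM_00433520 are neighbours and were both called higher with each nanoparticle. Among 7224 pairs of neighbouring tested genes, both members were called higher in 1 pair with silver ion, 2 with Ag-Cit10, 4 with Ag-Cit80 and 10 with Ag-PVP80. These 4 genes prompted the test, so they were left out of it. In the remaining 7222 pairs both members were called higher in 0 pairs with silver ion and Ag-Cit10, 2 with Ag-Cit80 and 8 with Ag-PVP80. Shuffling the calls 10000 times gave on average 0.158 such pairs for Ag-Cit80 and 0.689 for Ag-PVP80 (one-sided permutation p = 0.012 and 1e-04, the latter being the smallest these shuffles can give; adjusted p = 0.03 and 8e-04 over 8 tests). Both members were called lower in 7 pairs with Ag-Cit80 and 25 with Ag-PVP80, against 2.62 and 14.1 shuffled (adjusted permutation p = 0.03 and 0.018), and in 0 pairs with silver ion and Ag-Cit10. The gene models of these pairs do not overlap in the reference, but reads shared between similar neighbours could not be ruled out. The shuffles did not hold the level or length of genes fixed. Neighbours alike in these, or moving together between libraries, could therefore also give more pairs than shuffled.

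Genes called higher with Ag-PVP80 lay mostly among short genes and among genes of high level. With tested genes in 3 equal parts by length, 83 were higher and 117 lower in the part with the shortest models (median 888 bases), 35 and 219 in the middle part (median 1917) and 10 and 220 in the longest (median 4024). With Ag-Cit80 the numbers were 39 and 55, 18 and 91, and 6 and 94. In 3 equal parts by level, from low to high, 23, 24 and 83 genes were higher and 115, 196 and 246 lower with Ag-PVP80, and 8, 12 and 45 higher and 69, 89 and 82 lower with Ag-Cit80. Length and level were not tested apart. Lengths were taken from the reference, which may differ from the models behind the tables, and were found for 99.8% of tested genes.

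Libraries of one group split along the first principal component, with 1 library of the control and of each nanoparticle apart from the other 2. A dominant transcript that takes a varying share of the fragments would shift all other genes alike, but after scaling the slope of log2 level on the log2 scaling factor differed by -1.21 between the genes with the highest and those with the lowest level (-1.24 to -1.20 when 1 library was left out), which argues against it as the whole cause. Sequencing depth stays open: the value of 1 fragment differed at most 1.05-fold between libraries, yet too few low values were whole multiples for this to decide. The silver treatment was the same for all libraries of a group, so it cannot by itself part them. The untreated control split too, with replicate 1 at 0.183 and replicates 2 and 3 at -0.183 and -0.066. Both argue against the treatment as the cause of the split within groups. Whether it adds to differences between groups on this component stays open (one-sided permutation p = 0.27). A difference between cultures or preparation days could not be tested, as the labels give neither.

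Ag-Cit10 replicate 1 lay apart from Ag-Cit10 replicates 2 and 3, and without it limma called 309 genes against the control in place of 74. On 100 genes that separate the other Ag-Cit10 and Ag-PVP80 libraries, with 0 as the Ag-Cit10 level and 1 as the Ag-PVP80 level, its median position was 0.752 and that of Ag-PVP80 replicate 2 was 0.507. These tests of a wrong label or an exchange, set before their result was seen, do not decide, because the libraries used to pick the genes lie on opposite sides of the first principal component, with Ag-Cit10 replicate 1 on the Ag-PVP80 side. Among genes called between Ag-PVP80 and control where the other Ag-Cit10 libraries lay at least 1.3-fold beyond all 3 Ag-PVP80 libraries, replicate 1 also lay beyond them on that side in 76.8% (116 of 151) and Ag-Cit10 replicates 2 and 3, each held out in turn, in 98.6% and 93.4%, but among all tested genes these shares were 37.0% (296 of 800), 85.1% and 84.4%. This does not decide either: with replicate 1 counted among the Ag-PVP80 libraries and each of these 4 held out of the calls in turn, replicate 1 lay beyond in 64.1% (127 of 198), Ag-PVP80 replicate 2 in 91.2% of 567 genes and Ag-PVP80 replicates 1 and 3 in 11.7% and 12.3%. TTHERM_00784250 and TTHERM_00284090, named for their fall with Ag-PVP80, placed replicate 1 near its group, at 21.1 and 2.88 FPKM. Ag-Cit10 replicates 2 and 3 had at least 28.8 and 3.29 FPKM, and Ag-PVP80 at most 8.33 and 0.54. TTHERM_000440549 and TTHERM_00433520, at 27.3 and 59.45 FPKM, lay within the Ag-PVP80 ranges of 16.5 to 27.5 and 56.3 to 84.2 FPKM. These few genes do not settle the label, and the distance of replicate 1 from its group stays unexplained.

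TTHERM_00660230, TTHERM_00241640, TTHERM_00433530, TTHERM_00433520 and MXLOC_008985 were called higher with each nanoparticle than with silver ion. TTHERM_000440549 and TTHERM_00241650 were not called between silver ion and Ag-Cit10 or Ag-Cit80 (limma adjusted p = 0.101 to 0.191, though 0.0316 for TTHERM_00241650 with Ag-Cit80 without Ag-Cit80 replicate 3). For both, every nanoparticle library lay above every silver ion library, and scaling or the covariate gave some of these calls. The missed threshold thus does not show that they were not higher. For the first 5 genes a difference in scaling between libraries is argued against, since the smallest log2 difference over them and 3 nanoparticles was 1.98 (SE 0.19) after median-of-ratios scaling. One larger effective dose of silver from the nanoparticles may be a candidate explanation: of 59 genes higher and 142 lower with silver on average, 10 were called between nanoparticles and ion, and 0 of these lay nearer to the control with nanoparticles, while by sign alone 42 of the 59 and 116 of the 142 lay further from it. The signs of the falling genes lean the way of all tested genes, whose median log2 difference from silver ion was -0.17, -0.23 and -0.15 for Ag-Cit10, Ag-Cit80 and Ag-PVP80. TTHERM_00467520 goes against one larger dose for Ag-Cit80, at 49.1 ± 9.26 FPKM against 21.8 ± 6.31 with silver ion and 65.0 ± 4.75 in the control (limma adjusted p = 0.0488). Its means with Ag-Cit10 and Ag-PVP80, 33.4 ± 3.55 and 34.9 ± 7.05 FPKM, also lay nearer to the control than that with silver ion. The Ag-Cit80 call was lost in several settings. limma's adjusted p was 0.182 to 0.298 without silver ion replicate 2 or 3 or Ag-Cit80 replicate 1 or 2, and 0.0607 with the replicate block. It was 0.0599 with a pseudocount of 0.1, 0.108 with no filter on low values, 0.139 with only the 2 groups in the fit and 0.495 with the scaling factor as a covariate. By mean, TTHERM_01021930 and TTHERM_00070750 were nearer to the control with Ag-Cit10, at 106.6 and 42.7 FPKM, than with silver ion, at 49.0 and 20.6. The control had 105.8 and 58.1 FPKM. With Ag-Cit80 and Ag-PVP80 both were further from it than with silver ion. The lncRNA LXLOC_014336, at 0 in the control, was higher with silver ion (11.5 FPKM) than with the nanoparticles (2.76, 6.72 and 3.04 FPKM). After scaling, 65 of 83 genes higher and 127 of 218 lower with silver lay further from the control by sign. Of those called between nanoparticles and ion after scaling, 18 higher and 1 lower lay further and 2 lower nearer. Dose and form of silver cannot be told apart here, because each form was given at its own IC50, so a response to particles as such also stays open as an untested hypothesis. Doses at an IC50 are meant to match the forms in inhibition, and whether they did was not tested here.

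For each comparison of 3 against 3 libraries there are 10 splits of the 6 libraries, too few for a share under 0.05. For mRNA the real split was the 1 of 10 with the most calls in 8 comparisons. Against control the real and the highest other counts were 35 and 0 for silver ion, 74 and 0 for Ag-Cit10, 305 and 2 for Ag-Cit80 and 687 and 0 for Ag-PVP80. They were 19 and 0, 13 and 0, and 38 and 1 for the nanoparticles against silver ion and 5 and 1 for Ag-Cit80 against Ag-Cit10. For Ag-PVP80 against Ag-Cit80 all 10 splits gave at least the real 0, and one gave 3786, which points to a structure of these samples other than the groups. For lncRNAs the pairs were 2 and 0, 12 and 0, 25 and 10, and 39 and 0 against control, 0 and 0, 0 and 0, and 6 and 0 against silver ion, 0 and 1 for Ag-Cit80 against Ag-Cit10 and 0 and 391 for Ag-PVP80 against Ag-Cit80. Among 100 groupings of the 15 libraries, the real one with 21 genes changed the same way with all 4 forms was the 1 that reached this count, and the highest other had 0. The 8 genes differing the same way between each nanoparticle and silver ion were also reached in 1 of 100 groupings, the highest other having 2. A share of 1 in 100 is the smallest that these groupings can give. They argue against no difference at all between the 5 groups. They also mix control with silver libraries, which widens the spread, so they do not decide on nanoparticles against silver ion alone. Chance is not excluded for either count.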
